A study of Homo sapiens with 6 samples.

How the data were processed

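ATAC-seq libraries were made from 3T3-L1 cells at baseline (0 h), after 4 h with dexamethasone and after 4 h with DHA, 2 libraries each, and sequenced as read pairs, per the labels' protocols. A DNase step on whole cells preceded lysis and transposition, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt, Bowtie2, Picard, SAMtools and MACS2 and the mouse build mm9, with no versions, roles or order. The deposited table holds raw counts, not normalised, for 65378 regions of 500 bp on the autosomes and chromosome X. Its columns are named, per the file headers, for alignments without mitochondrial reads, filtered and with duplicates removed. The name of the table says that it was made after a filter; its rule, whether peaks were called per sample or on pooled samples, and whether reads, fragments or transposase insertions (with or without the usual shift of read ends to the insertion site) were counted are not given in the sources used here. A region enters the table only if the authors kept it, so accessibility that fell outside their regions was not analysed here, and a region set called on all groups or on one group would favour different changes.

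Totals of the deposited counts ran from 4526237 to 6251633 per library, with medians of 39 to 57 counts per region. These totals cover the listed regions only and are not the depth of the whole libraries. A region with few counts can show only large changes: rises called with dexamethasone had a median of 2.51-fold in the lowest accessibility quartile and 1.42-fold in the highest. Data were also simulated from these libraries' means and sizes and edgeR's fitted dispersion, with 200 of 65371 regions changed, not split by counts. The test recovered 28% of 1.5-fold and 67% of 2-fold changes for dexamethasone against the baseline, with 3 false calls. For DHA against the baseline it recovered 31% and 65%, with 1 false call. A far larger share of regions was called with dexamethasone in the data, which moves the adjusted threshold, so these shares do not give the recovery there.

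Replicates were compared first, by a chi-square test of the counts of each pair. Chi-square per degree of freedom, which noise alone spreads around 1 with an SD of 0.0055, was 1.04 for the baseline pair and 1.10 for the DHA pair. The 2 dexamethasone libraries, at 0.995, showed no difference over all regions, so they were summed and counted as 1 sample. In the octile of regions with most counts their value was 1.05, above noise (SD 0.0154 over 1000 binomial draws), and 1.01 once the share of each library was refitted there; the baseline pair gave 1.06 and 1.05. This departs from the fit fixed before the data were examined, in which all 6 libraries entered separately; it was chosen after the counts and the calls of that fit had been seen, and the fit with 6 libraries is given as an alternative. No label says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. All 5 samples entered one fit in edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr by group (65371 regions tested), a quasi-likelihood fit without the robust option, 2 residual degrees of freedom and Benjamini-Hochberg adjustment over tested regions, two-sided, called at an adjusted p under 0.05. The lone dexamethasone sample is assumed to vary like the other groups. The common dispersion corresponded to a coefficient of variation of 2.46% between samples beyond counting noise. SE is the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled in the usual way of CPM to the TMM-adjusted total of the listed regions.

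Regions named in the text followed a rule fixed before the data were examined: per comparison and direction, the 10 called regions with the largest log2 fold change among those at or above the median mean accessibility and with both libraries of one group above both of the other, the region with the smallest p, and the 3 runs with most members. Runs are at least 3 regions called in one direction with gaps of at most 50 kb, set beside 1000 seeded random draws of tested regions matched on chromosome. The draws were not matched on accessibility and treated regions as independent, though neighbours can start as little as 503 bp apart. Calls were counted per quartile of mean log2 CPM over all samples, with exact binomial intervals at 95%, which cover counting error only. For the comparisons that share the baseline libraries, 20 sets of unchanged groups were simulated, and the covariance and correlation were set beside the observed values. All samples of a set, the baseline libraries included, were drawn anew from the mean baseline levels with edgeR's fitted dispersion. A further 40 sets, added after the results were seen, kept the fitted changes of dexamethasone and shuffled those of DHA over regions of like accessibility, with changes at called regions alone in 20 sets and at all regions in the other 20. With changes at all regions these sets held more DHA calls than the data (means of 4555.8 and 3380.9), so shares of calls were compared, not counts.

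Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, no scaling beyond library size, loess offsets, no filter and a stricter filter on low counts (CPM of 1 in 2 samples and a mean count of 20), a test against a 1.5-fold change (glmTreat), an adjusted p under 0.01, only the groups compared, autosomes only, the replicate letter as a block and each library left out in turn. The gene table at hand describes the human genome and was not used, since the regions lie on a mouse build; no mouse genome sequence or annotation was used here. Genes, gene lists and sequence motifs, which had been planned, were therefore not analysed here. Figures were drawn with matplotlib 3.10.9.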

Results

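Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 3T3-L1 cells. This is an established mouse line of preadipocytes that turn into fat cells when given differentiating agents; the labels name human as the organism, but the line and the genome build of the coordinates, mm9, are mouse. The 6 libraries fell into 3 groups of 2. Baseline cells (0 h) had been kept at confluence in calf serum. The other groups were taken 4 h after a change to fetal bovine serum with either dexamethasone at 1 µM, a synthetic glucocorticoid, or DHA at 100 µM. The labels do not spell out DHA; from the study it is taken as docosahexaenoic acid, an omega-3 fatty acid. No 4 h library without an agent was analysed here, so each comparison with the baseline holds the agent, the elapsed time and the serum change together, while DHA against dexamethasone compares cells at the same time and in the same serum.

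Counts were given for 65378 regions of 500 bp on 20 chromosomes. The counts inside these regions summed to 4792569 and 5204963 in baseline replicates a and b, 4567300 and 6251633 with dexamethasone, and 5571701 and 4526237 with DHA. Over all regions the 2 dexamethasone libraries differed by less than the sampling noise (chi-square per degree of freedom 0.995, p = 0.797) and were counted as 1 sample, by summing their counts. The baseline pair (1.04) and the DHA pair (1.10) differed by slightly more than noise. In the octile of regions with most counts the dexamethasone pair was above noise too (1.05, where noise has an SD of 0.0154), near the baseline pair (1.06). With the share of each library refitted in that octile, they were at 1.01 and 1.05. Dexamethasone levels therefore carry no SD, and levels of the other groups are mean ± SD with n = 2 in normalised counts as CPM, scaled to the total of the listed regions. Regions are named by position in mm9, since no mouse gene annotation was used here.

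The first comparison asked which regions opened or closed 4 h after dexamethasone. Accessibility rose at 9730 of 65371 tested regions (14.9%) and fell at 7882 (12.1%; edgeR quasi-likelihood test, adjusted p under 0.05). The median rise was 1.92-fold and the median fall 1.66-fold; 4438 of the risen regions and 1574 of the fallen ones changed by more than 2-fold. The median baseline level, which is also the denominator of the fold, was 5.84 CPM for risen regions, 14.3 CPM for fallen ones and 9.05 CPM for all tested regions. The shares in the top quartile were 16.2% of rises and 35.8% of falls by baseline level, 21.9% and 27.8% by mean accessibility over all samples, and 25.0% and 27.6% with loess offsets, so the size of this gap depends on the measure. DESeq2 called far fewer regions, 1632 higher and 609 lower, and a test against a 1.5-fold change called 3435 and 1022. Without baseline replicate a the fallen regions numbered 5074, and without dexamethasone replicate b 5185.

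The region with the largest named rise lies on chromosome 13, 47656569 to 47657068. It went from 1.74 ± 1.59 CPM at baseline to 44.4 CPM with dexamethasone, a log2 fold change of 4.62 ± 0.23 (SE; edgeR adjusted p = 1.3e-30); its baseline counts were 3 and 15, so the size of the fold is loosely fixed. Chromosome 17, 84634727 to 84635226, rose 16.6-fold from 1.39 ± 0.08 to 23.4 CPM. Chromosome 19, 33136706 to 33137205, rose 12.7-fold from 1.86 ± 0.88 to 24.3 CPM. The remaining 7 of the 10 risen regions named by the preset rule rose 9.35-fold to 12.1-fold. They include regions of chromosome 6 starting at 99125189, 115188557 and 115469348, and 2 of chromosome 2, starting at 124597743 and 128296040. The smallest p among risen regions belonged to chromosome 5, 107648240 to 107648739, which went from 14.9 ± 0.56 to 86.2 CPM (5.78-fold, edgeR adjusted p = 3.3e-33). Of these 10 regions, 3 were also called higher with DHA against the baseline, and all 10 were higher with dexamethasone than with DHA.

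Among falls, chromosome 17, 35956703 to 35957202, went from 18.9 ± 0.90 CPM to 4.30 CPM, a log2 fold change of -2.13 ± 0.22 (SE; edgeR adjusted p = 1.3e-13). Chromosome 1, 151697221 to 151697720, went from 18.8 ± 2.05 to 4.76 CPM (3.93-fold lower), and chromosome 2, 46508001 to 46508500, from 23.7 ± 0.20 to 6.17 CPM (3.84-fold lower). The 10 named falls spanned 3.40-fold to 4.38-fold, and 7 of these regions were called lower with DHA as well. The smallest p was at chromosome 18, 57326975 to 57327474, which went from 70.7 ± 1.90 to 29.1 CPM (2.43-fold lower, edgeR adjusted p = 9.3e-19).

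Regions that moved under dexamethasone lay together along chromosomes. Of the risen regions, 43.7% stood in 966 runs of at least 3 with gaps of at most 50 kb, against 30.0% for random draws of as many regions matched on chromosome. Fallen regions formed 672 runs holding 34.3%, against 22.9% at random (for both, permutation p = 0.001, the smallest that 1000 draws can give). The draws treated neighbouring regions as independent and were not matched on accessibility. The run of rises with most members spanned chromosome 17, 84284941 to 84821940, where 30 of 70 tested regions rose and 2 fell. The next were chromosome 8, 122487959 to 122907190, with 26 of 52 regions higher, and chromosome 2, 27522983 to 27795935, with 19 of 47. The runs of falls with most members had 15 each, on chromosome 2 from 168253923 to 168433611, on chromosome 4 from 88573972 to 88735381 and on chromosome 17 from 45872039 to 46043009. Narrowing the allowed gap to 20 kb left 558 and 325 runs.

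**Figure D1:**
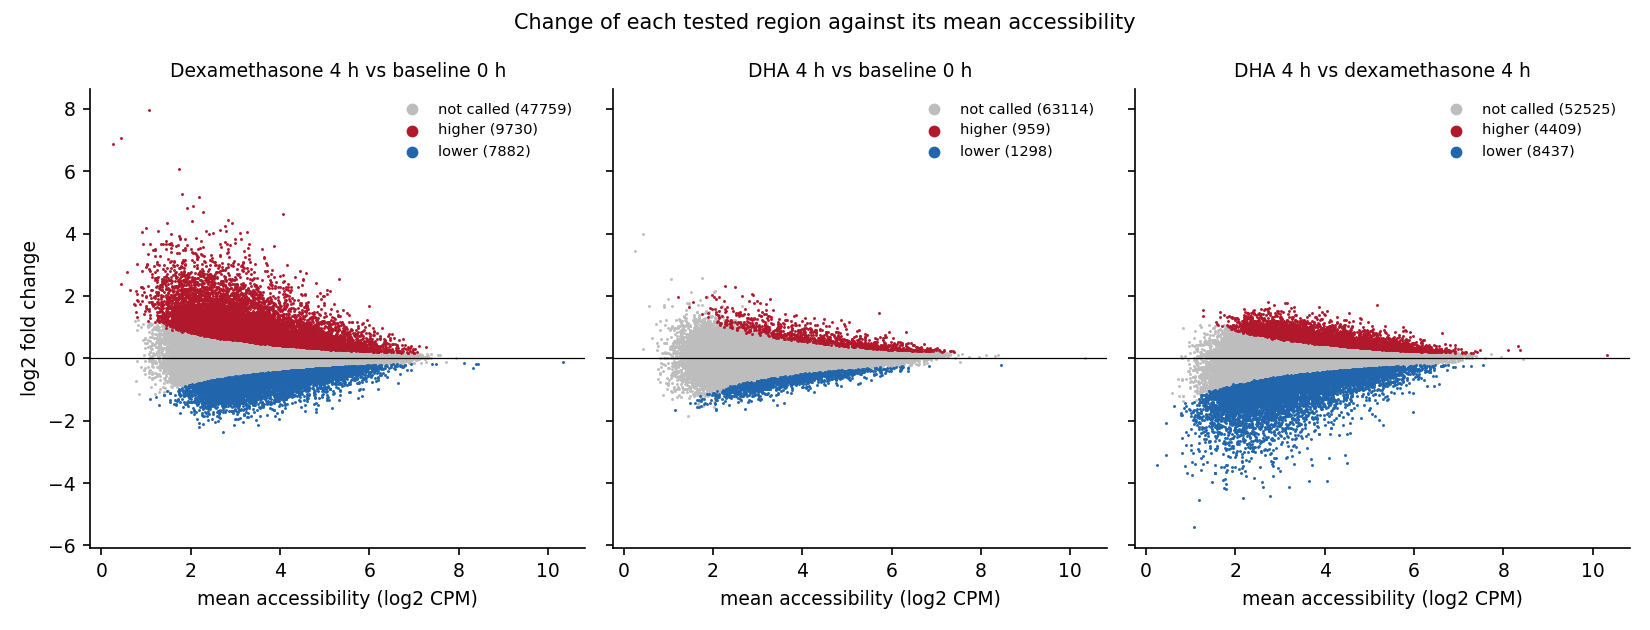
Log2 fold change (vertical axis) of each of the 65371 tested regions against its mean accessibility in log2 CPM (horizontal axis), for the 3 comparisons; red and blue points are regions called higher and lower, grey points are not called, with numbers in the key. Dexamethasone gave 9730 higher and 7882 lower regions against the baseline and DHA 959 and 1298; the few points far from 0 at the left rest on few counts.

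The second comparison asked the same of DHA. Accessibility rose at 959 regions (1.47%), by a median of 1.52-fold, and fell at 1298 (1.99%), by a median of 1.63-fold (edgeR quasi-likelihood test, adjusted p under 0.05). Changes above 2-fold were few, 183 higher and 180 lower. These counts depended on the libraries that entered: they fell by more than 1.5 times without baseline replicate a, baseline replicate b or DHA replicate a. They stayed within 1.5 times without DHA replicate b or either dexamethasone library. Leaving out a baseline or DHA library also leaves a lone sample in its group and less power, so a fall in calls may come partly from that. Either DHA library left out gives the same design, so the lone sample does not explain why only the fit without replicate a fell so far. Replicate b, then left alone, is the smaller library. Without replicate b the counts stayed near, but part of the called regions changed. DESeq2 called 31 and 6 regions, a test against a 1.5-fold change called 5 and 1, and at an adjusted p under 0.01 edgeR called 381 and 401.

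The largest named rise with DHA was on chromosome 2, 128296040 to 128296539, from 1.70 ± 0.52 CPM to 6.31 ± 0.48 CPM, a log2 fold change of 1.90 ± 0.35 (SE; edgeR adjusted p = 0.00027). It was followed by chromosome 5, 21035127 to 21035626, which rose 2.90-fold from 4.63 ± 1.57 to 13.6 ± 0.11 CPM. Chromosome 4, 5511309 to 5511808, rose 2.74-fold from 26.2 ± 0.77 to 71.6 ± 7.33 CPM and had the smallest p of the comparison (edgeR adjusted p = 9.2e-20). The 10 named rises spanned 2.47-fold to 3.72-fold, and all 10 of these regions were called higher with dexamethasone too. At 2 of them the call ended when DHA replicate a was left out: chromosome 2 from 124597743, where edgeR's adjusted p became 0.563, and chromosome 12 from 110152419, where it became 0.0769; the first was lost without baseline replicate b as well (edgeR adjusted p = 0.145). DESeq2 with the dexamethasone libraries separate did not call 5 of the 10, and the test against a 1.5-fold change did not call 9. With those libraries summed, DESeq2 gave no adjusted p for 18 of the named rises and falls with DHA, so it could not bear them out.

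The largest named fall with DHA was on chromosome 1, 40911874 to 40912373, from 19.1 ± 2.91 CPM to 6.73 ± 0.14 CPM, a log2 fold change of -1.49 ± 0.20 (SE; edgeR adjusted p = 2.7e-07). Chromosome 15, 53383707 to 53384206, fell 2.67-fold from 19.6 ± 2.26 to 7.65 ± 4.21 CPM, and chromosome 6, 134646915 to 134647414, fell 2.54-fold from 17.9 ± 1.86 to 7.09 ± 0.62 CPM. Of the 10 named falls, between 2.18-fold and 2.81-fold, 9 were at regions called lower with dexamethasone. The exception, chromosome 11, 67458029 to 67458528, fell from 10.3 ± 0.02 to 4.62 ± 0.59 CPM with DHA and stood at 11.8 CPM with dexamethasone. One named fall, chromosome 6 from 7423002, was not called without baseline replicate a (edgeR adjusted p = 0.0605). DESeq2 with the dexamethasone libraries separate did not call 7 of the 10, among them chromosome 15 from 53383707 (DESeq2 adjusted p = 0.343) and chromosome 11 from 67458029 (DESeq2 adjusted p = 0.316), and the test against a 1.5-fold change did not call 9.

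**Figure D2:**
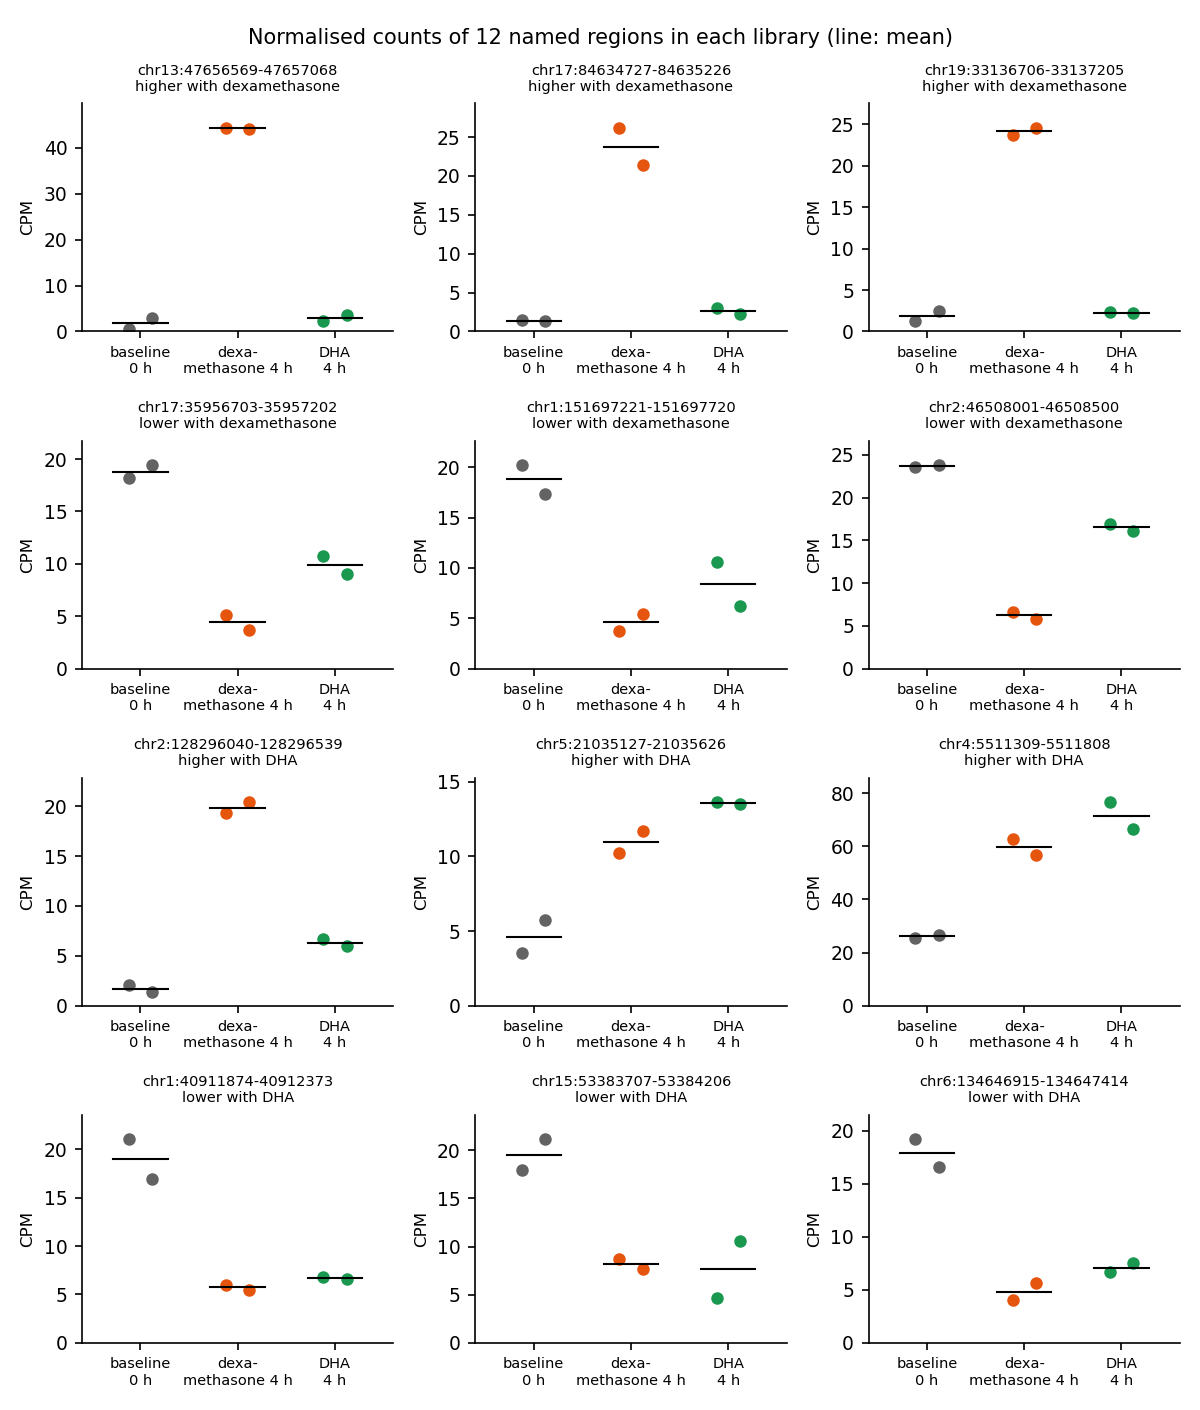
Normalised counts as CPM (vertical axes, each starting at 0) in each of the 6 libraries, by group, for the 3 named regions with the largest change per direction under dexamethasone (upper 2 rows) and DHA (lower 2 rows), all against the baseline; points are libraries and lines are means of 2 libraries, which for dexamethasone count as 1 sample. Chromosome 13 from 47656569 reached 44.4 CPM with dexamethasone against 2.94 CPM with DHA, while chromosome 4 from 5511309 was above its baseline of 26.2 CPM with both agents.

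Rises with DHA also lay together: 29 runs held 11.1% of them, against 0.72% at random, and 18 runs held 5.24% of the falls, against 1.24% (for both, permutation p = 0.001, the smallest that 1000 draws can give). Here too the draws treated neighbouring regions as independent and were not matched on accessibility, so part of the excess may come from that. The run of rises with most members, on chromosome 11 from 74795208 to 74865508, held 7 of 11 tested regions, with a median log2 fold change of 0.89. Of these, 5 were called higher with dexamethasone. The run of falls with most members, on chromosome 2 from 168352985 to 168433611, held 8 of 10 tested regions, and all 8 were called lower with dexamethasone, with a median log2 fold change of -0.56 under DHA and -1.06 under dexamethasone. Of the risen regions, 58.9% (95% exact binomial interval 55.7% to 62.1%) were in the quartile of highest mean accessibility, against 28.7% (26.3% to 31.3%) of the fallen regions. With loess offsets, which remove trends with accessibility between libraries, the shares were 39.4% and 45.1%, and with quartiles of the baseline libraries alone they were 46.6% (43.4% to 49.8%) and 42.4% (39.7% to 45.2%). The difference was thus reversed with loess offsets, and small and in the same direction with baseline quartiles.

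**Figure D3:**
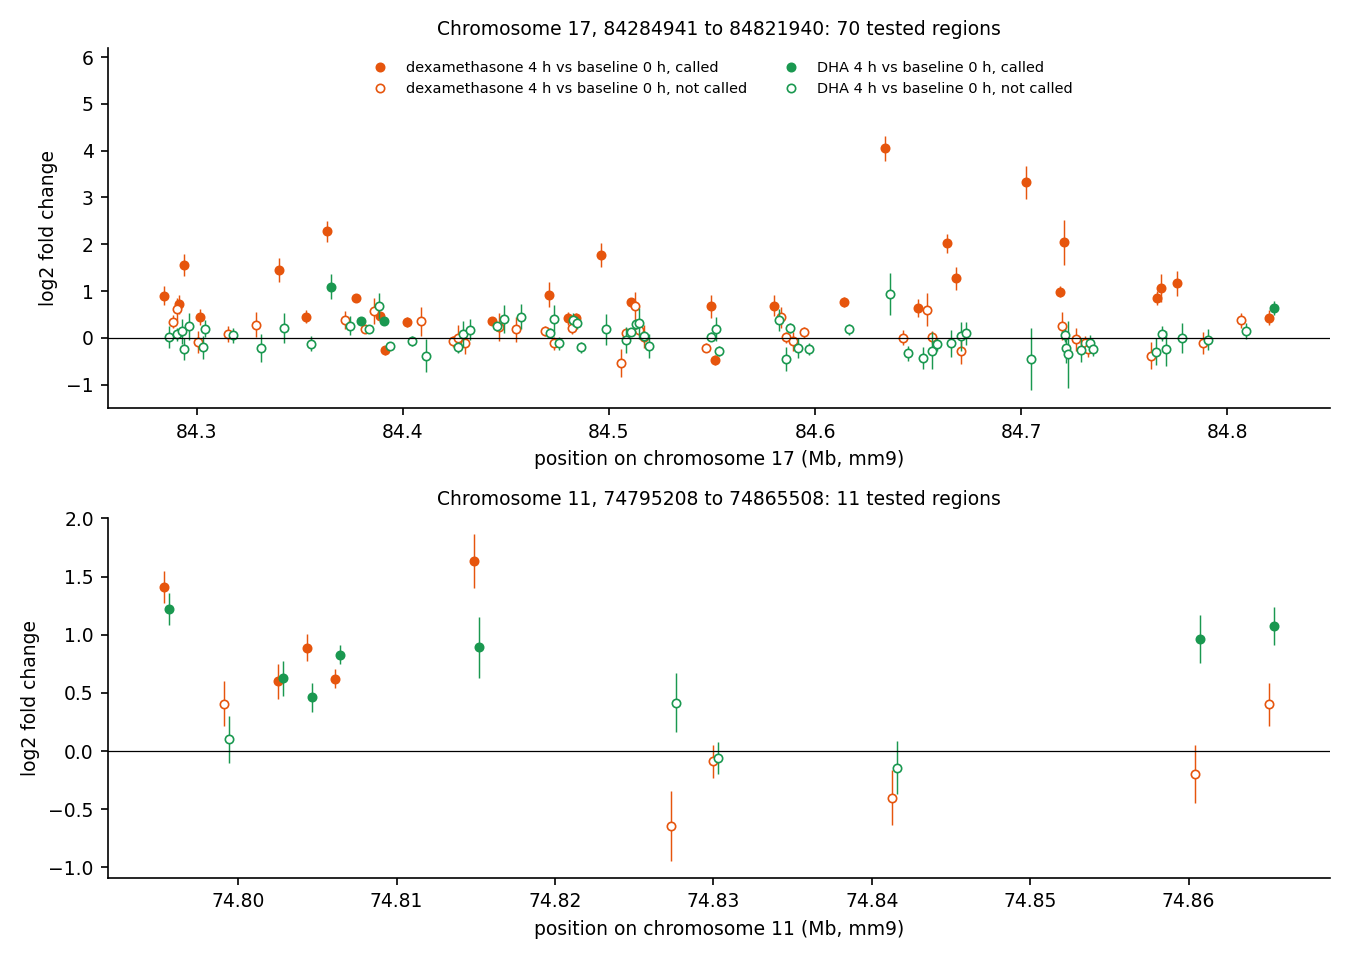
Log2 fold change ± SE (vertical axes) of each tested region along 2 stretches of mm9 (horizontal axes, position in Mb), for dexamethasone (orange) and DHA (green) against the baseline; filled points are called regions and open points are not, and the pair of points of a region is set slightly apart. On chromosome 17, 30 of 70 regions were called higher with dexamethasone, and on chromosome 11, 7 of 11 were called higher with DHA, 5 of them with dexamethasone too.

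Both comparisons with the baseline were then set side by side. In both comparisons 610 regions were called higher and 930 lower, which is 63.6% and 71.6% of the regions called with DHA. Independent lists of these sizes would share 143 and 157. In simulations where both agents changed regions unrelated to each other and shared the baseline, at most 19.03% and 29.75% of the regions called with DHA were in common. Opposite calls numbered 20 (higher with dexamethasone) and 5 (lower). Independent lists would give 193 and 116, but the shared baseline can lower such calls by itself. The simulations with changes at called regions gave means of 54.45 and 96.45, with fewer DHA calls than in the data (means of 841.05 higher and 715.1 lower). Those with changes at all regions gave means of 289.75 and 643, with more DHA calls than in the data. The covariance of the log2 fold changes over regions was 0.105, against 0.0316 in simulations of unchanged groups that shared redrawn baseline libraries (highest of 20, 0.0327). Pearson's r over regions was 0.505 against 0.503 in the latter simulations, and 67.5% of regions had the same sign against 66.6%; regions are not independent replicates. The 2 baseline libraries leave only 1 each when split, so part of the excess in shared calls may come from the shared baseline. Without baseline replicate a the regions in common were 251 and 265, without baseline replicate b 325 and 472, and without DHA replicate a 276 and 308; DESeq2 left 22 and 2.

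**Figure D4:**
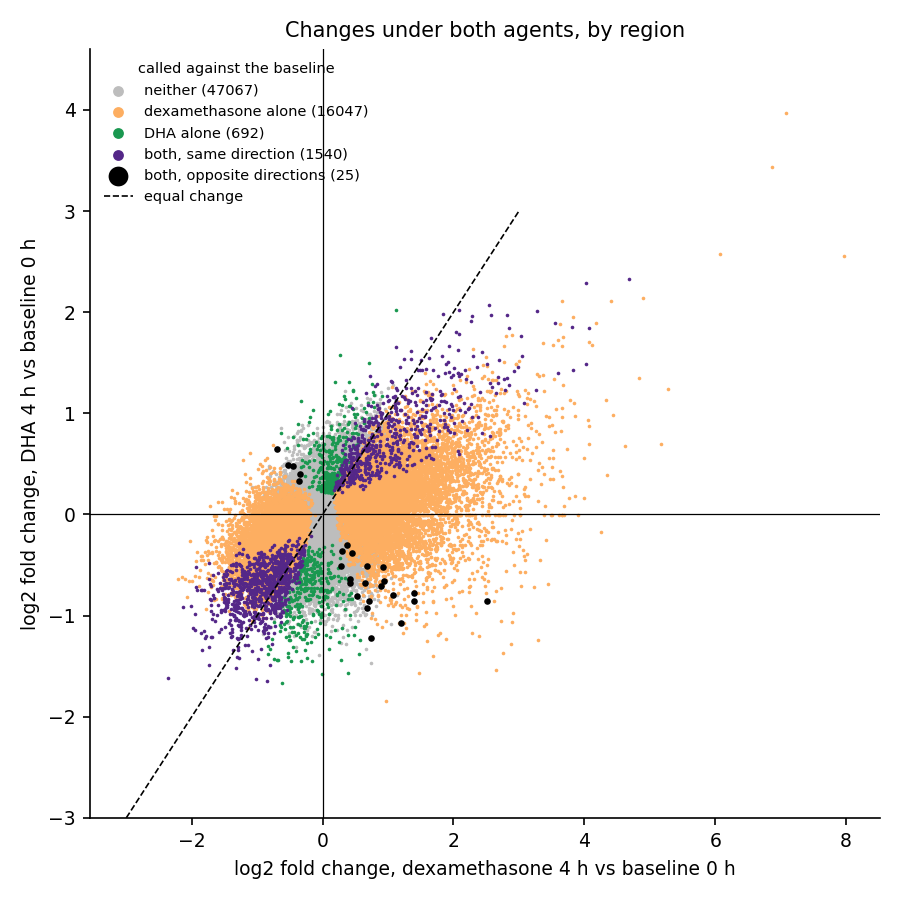
Log2 fold change under DHA (vertical axis) against that under dexamethasone (horizontal axis), both from the same baseline, for each of the 65371 tested regions; colours show in which comparison a region was called and the dashed line marks equal change. Regions called in both lie mostly in the same direction, 1540 against 25; the points farthest to the right rest on few baseline counts.

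The third comparison, DHA against dexamethasone, asked how the agents differed at the same time and in the same serum. Accessibility was higher with DHA at 4409 regions (6.74% of those tested), by a median of 1.55-fold, and lower at 8437 (12.9%), by a median of 1.92-fold (edgeR quasi-likelihood test, adjusted p under 0.05). Most of these were regions called for dexamethasone against the baseline and where DHA was not called: 6461 that rose and 2727 that fell with dexamethasone. Both comparisons use the same summed dexamethasone sample, whose own deviations push these calls together, and no simulation was set beside this overlap. At regions higher with dexamethasone the median log2 fold change was 0.94 under dexamethasone and 0.20 under DHA; at regions lower with dexamethasone it was -0.73 and -0.29. These regions were chosen by their change from the same baseline libraries, which pulls the DHA values the same way: the simulations with unrelated changes gave DHA medians of up to 0.07 and down to -0.07. Of the 1540 regions moved in common, 378 (24.5%, 95% exact binomial interval 22.4% to 26.8%) also differed between the agents, 204 risen and 163 fallen ones with the larger change under dexamethasone and 11 risen ones with the larger change under DHA. DESeq2 called 113 regions higher and 786 lower with DHA. The higher calls numbered 2328 without dexamethasone replicate b and 2532 without DHA replicate a.

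The largest named excess of dexamethasone over DHA was on chromosome 3, 59971661 to 59972160, at 30.8 CPM with dexamethasone, 2.00 ± 0.29 CPM with DHA and 3.28 ± 0.05 CPM at baseline (log2 fold change -3.94 ± 0.23, SE; edgeR adjusted p = 7.6e-26). Chromosome 17, 24694046 to 24694545, stood at 30.6 CPM with dexamethasone, 2.83 ± 0.57 CPM with DHA and 4.85 ± 0.71 CPM at baseline. The smallest p was at chromosome 17, 32034023 to 32034522, with 53.3 CPM under dexamethasone and 5.05 ± 1.5 CPM under DHA (10.3-fold lower, edgeR adjusted p = 2.4e-30). All 10 named regions lower with DHA than with dexamethasone had risen with dexamethasone against the baseline. The 10 named regions higher with DHA had all fallen with dexamethasone. This agreement, too, rests partly on the dexamethasone sample that both comparisons share. The first of them, chromosome 5, 4240027 to 4240526, stood at 43.7 ± 1.46 CPM at baseline, 14.5 CPM with dexamethasone and 47.5 ± 3.98 CPM with DHA (3.30-fold higher than with dexamethasone, edgeR adjusted p = 1.3e-19); its neighbour from 4231633 stood at 4.11 CPM with dexamethasone and 12.7 ± 3.32 CPM with DHA. The run with most members among regions lower with DHA than with dexamethasone, chromosome 11 from 67263732 to 67400161, held 17 of 29 tested regions, and that among higher ones, chromosome 2 from 102647932 to 102821959, held 10 of 26.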

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

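The test of a duplicated library and the test of power at higher counts were chosen after the result was seen, as was the split of the regions moved in common by whether the agents differed.

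Against the same baseline, 20 regions rose with dexamethasone and fell with DHA, and 5 fell with dexamethasone and rose with DHA. They stand out because the changes from the baseline differed in sign; these hold the agent, the elapsed time and the serum change together, so opposite effects of the agents themselves are not shown. The widest gap was at chromosome 17, 32034023 to 32034522, which stood at 9.31 ± 1.16 CPM at baseline, 53.3 CPM with dexamethasone and 5.05 ± 1.5 CPM with DHA (SD, n = 2). The 5 regions that rose with DHA start on chromosome 1 at 120265183, chromosome 2 at 11287124, chromosome 3 at 102170086, chromosome 10 at 98699824 and chromosome 16 at 31475458. The number rests on single libraries: 2 such regions were called without baseline replicate a, 1 without baseline replicate b and 4 without DHA replicate a, all of them higher with dexamethasone, while 40 were called without DHA replicate b and 15 without dexamethasone replicate b.

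Changes under the agents went together, with a covariance of 0.105 that lay above all 20 values simulated for shared baseline libraries (mean 0.0316). Pearson's r, at 0.505, was near the simulated 0.503. The simulated libraries varied only by counting noise and edgeR's fitted dispersion, so that spread is not the whole of it. A deviation common to both baseline libraries was not simulated, so the shared baseline stays open. A bias between libraries that depends on accessibility would shrink the shared calls once removed, and loess offsets gave 615 and 786, at least 0.845 of the number in each direction, of which 518 and 673 were among the original 610 and 930 (without baseline replicate a, baseline replicate b or DHA replicate a the shared calls were 251 and 265, 325 and 472, and 276 and 308). The serum change and elapsed time alone would make the agents alike, yet 24.5% of the regions moved in common also differed between them, mostly with the larger change under dexamethasone. Over all tested regions 6.74% were higher and 12.9% lower with DHA than with dexamethasone, so such differences are not particular to the regions moved in common. The 24.5% shows only that the agents were not alike at those regions. It does not measure how much of the common changes came from serum and time. For the other 1162 regions the serum change and time cannot be told apart from an effect of both agents, because no 4 h library without an agent is among the 6, and their contribution to the rest stays open too.

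Rises with DHA concentrated in the quartile of highest accessibility (58.9%). Power at higher counts would concentrate falls alike, and 28.7% of falls were there, but with quartiles of the baseline libraries alone the shares were 46.6% and 42.4% with overlapping intervals. Overlap is not a test of this smaller gap, so power stays open and the size of the pattern depends on how accessibility is measured. A difference in signal to background between libraries may explain the pattern: with loess offsets the share of rises was 39.4%, below that of falls at 45.1%. A biological shift at the most accessible regions stays open, since loess offsets would remove it as well.

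The dexamethasone libraries differed by no more than sampling noise over all regions (chi-square per degree of freedom 0.995), while the baseline and DHA pairs were at 1.04 and 1.10. In the top octile of regions by counts the value was 1.05, which is 3.36 SD above noise and near the 1.06 of the baseline pair, against 0.987 in the rest. With the share of each library refitted in that octile it was 1.01, 0.92 SD above noise, against 1.05 and 3.25 SD for the baseline pair, so the excess was mostly one shift common to these regions. Whether one library was sequenced again, or these are separate libraries from one culture or from cultures that differ very little, stays open, because each may give such a shift.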

How the results depend on the processing

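The fits with the dexamethasone libraries separate and the loess quartile shares were chosen after seeing the data. In each pair of counts the regions that were higher come first. DESeq2 called, of regions, 1632 and 609 for dexamethasone, 31 and 6 for DHA, 113 and 786 for DHA against dexamethasone, and 22 and 2 in common; with the dexamethasone libraries separate it called 4098 and 2126, 58 and 12, 629 and 2749, and 48 and 11. Its median fitted dispersion was 0.0521 against 0.00125 for edgeR's trend, and on simulated data it recovered 14% of 2-fold changes for dexamethasone against 67%. Those data were drawn with edgeR's fitted dispersion, which favours edgeR, so they cannot tell which spread is right. The replicates can in part: chi-square per degree of freedom was 1.04 for the baseline pair and 1.10 for the DHA pair, little above counting noise. That argues against a spread between these libraries as wide as DESeq2's. Whether separate cultures would vary more stays open. For DHA, DESeq2 gave no adjusted p for 44359 regions, 1066 of them called by edgeR, which are not counted as lost. The test against a 1.5-fold change, which asks for more than any change, called 3435 and 1022, 5 and 1, 172 and 2476, and 5 and 1. An adjusted p under 0.01 gave 4848 lower for dexamethasone, 381 and 401 for DHA, 2134 higher for DHA against dexamethasone, and 254 and 313 in common. Counting a region as common when called in one comparison with an unadjusted p under 0.05 in the other gave 2101 and 3153.

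Leaving out each library in turn gave 5074 to 8500 lower regions for dexamethasone, 348 to 1006 higher and 346 to 1304 lower for DHA, 2328 to 4191 higher for DHA against dexamethasone, and 251 to 545 and 265 to 827 in common; a lone sample is then assumed to vary like the other groups, and fewer samples enter. DHA counts were lowest without baseline replicate a; those without baseline replicate b and DHA replicate a were 471 and 616, and 383 and 389. The covariance ranged from 0.0991 to 0.153 and was 0.0653 over regions above the median accessibility; the correlation ranged from 0.419 to 0.589. The cause of these moves was not tested.

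With the 6 libraries separate, as fixed before the data were examined, edgeR called 10185 and 8344 for dexamethasone, 1124 and 1467 for DHA, 4936 and 8878 between the agents, and 707 and 1062 in common, all within 1.5 times. The replicate letter as a block, with libraries separate, gave 10252 and 8484 for dexamethasone, 1151 and 1541 for DHA, and 4946 and 8858 between the agents, within 1.5 times of the counts without it. The correlations of a minus b between groups were -0.01, 0.03 and 0.002. Differences between replicates were nearly all counting noise, so these values cannot tell whether the letters pair the samples.

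Shares in the top accessibility quartile by baseline libraries alone were 16.2% and 35.8% for dexamethasone, 46.6% and 42.4% for DHA, and 48.1% and 13.8% between the agents; with loess offsets they were 25.0% for rises with dexamethasone, 39.4% and 45.1%, and 30.5% and 25.6%. Runs with gaps of at most 20 kb numbered 558 and 325, 17 and 11, and 114 and 417; at most 100 kb gave 36 runs of falls with DHA and 371 of regions higher with DHA than with dexamethasone. Other alternatives stayed within 1.5 times of each count. For the 62 named values under 18 alternatives, 1064 of 1098 kept direction and call, 34 lost the call and none reversed. All 34 were among the 20 named for DHA against the baseline: 18 under the 1.5-fold test, 12 under DESeq2 with libraries separate and the rest with a library left out. DESeq2 with the dexamethasone libraries summed gave no adjusted p for 18 more values, all of them for these 20 regions. No scaling moved the median of all regions by over 0.1. Gene lists and motif classes were not run, for want of a mouse reference. Regions near the lowest counts can show only large changes at this depth.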

Other observations

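The regions below were chosen after their values were seen, and no explanation was tested for them.

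Some regions moved with DHA and differed from dexamethasone in the direct test while dexamethasone itself was not called against the baseline: 176 higher, by a median of 1.43-fold with DHA, and 158 lower, by a median of 1.69-fold, with median log2 fold changes under dexamethasone of 0.04 and -0.02. These small medians follow in part from the choice of regions, and both tests use the same DHA libraries. The top accessibility quartile held 65.3% of these rises and 30.4% of these falls. On chromosome 5, 91320286 to 91320785, accessibility was 40.8 ± 3.87 CPM at baseline, 41.1 CPM with dexamethasone and 64.4 ± 1.17 CPM with DHA (SD, n = 2). On chromosome 15, 32606290 to 32606789, it was 5.60 ± 1.16, 7.38 and 13.8 ± 0.77 CPM, a 2.47-fold rise with DHA. On chromosome 11, 115817922 to 115818421, it fell from 43.7 ± 1.21 CPM to 24.6 ± 2.07 CPM with DHA and stood at 44.5 CPM with dexamethasone. A neighbouring region, 115816472 to 115816971, was one of those moved in opposite directions, with 39.0 ± 0.24 CPM at baseline, 53.2 CPM with dexamethasone and 29.7 ± 2.53 CPM with DHA. On chromosome 4, 5487160 to 5487659, near the region with the smallest p for DHA, accessibility rose from 23.3 ± 0.51 to 37.4 ± 0.97 CPM with DHA and was 21.4 CPM with dexamethasone. The numbers of such regions were 60 and 37 without baseline replicate a, 77 and 71 without baseline replicate b, 64 and 45 without DHA replicate a, and 100 and 96 without dexamethasone replicate b. With loess offsets 118 and 133 were called, of which 94 and 106 were among the original ones.

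After taking off the covariance and variance of the simulated unchanged groups, the change under DHA per unit of change under dexamethasone was 0.23 on the log2 scale, over all tested regions. At regions that fell with dexamethasone, 88.6% had a negative log2 fold change under DHA, against 71.8% with a positive one at regions that rose. Both shares include the pull of the shared baseline libraries; in simulations where the changes under the agents were unrelated, the shares reached at most 58.7% and 58.4%.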
